A study of Mus musculus with 9 samples.

How the data were processed

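Gene expression was measured in 3T3-L1 adipocytes, a mouse preadipocyte line that is differentiated into fat cells in culture. Mature cells were transduced with lentivirus that carried a scrambled control hairpin or 1 of 2 short hairpins against Ebf1, a transcription factor of the early B cell factor family. Per the labels' protocols, cells went through 3 to 4 serial infections and were kept in 5 µg/ml puromycin, which kills untransduced cells, for at least 8 days before harvest. Total RNA was amplified with a NuGEN whole-transcriptome kit for very small inputs and labelled with biotin, per the labels' protocols. The 9 arrays fall into 3 groups of 3 named in the titles: scrambled, hairpin 1 and hairpin 2. The titles number the arrays of a group as repeats and do not say whether these came from separate cultures. The p-values therefore measure the spread between these arrays, which may be technical.

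The deposited values are on a log2 scale, 1 value per probe set and array. The authors computed them with RMA, per the submitters' processing notes, which give no version; RMA subtracts background, equalizes the arrays and summarizes the probes of a probe set. The platform table used for gene names is that of an Affymetrix mouse expression array whose probe sets lie mostly near the 3' ends of transcripts. The table holds 45101 probe sets, of which 64 are controls and were left out. Of the others, 34945 name 1 gene symbol, 932 name several and 9160 name none. Only probe sets with 1 symbol were used for genes. The Entrez identifiers of 34741 of them were found in a gene table of assembly GRCm38.p6, and 0 symbols needed an update. No coordinates are given, because no genome build is named for the array values. Every value column belonged to a sample, with 0 columns left over.

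Values lay between 3.90 and 15.0 on the log2 scale, and array medians between 6.31 and 6.38. Pearson correlations over the genes tested were 0.994 to 0.998 within groups and 0.974 to 0.989 between groups. The median standard deviation of a gene within a group was 0.066 for scrambled, 0.118 for hairpin 1 and 0.0929 for hairpin 2. For 31.1% of genes at least 2 of the 9 arrays held the same value to the last digit given, which happened within a single group for 4.33% to 6.73% of genes and on all 3 arrays of a group for at most 0.448%. No pair of arrays held the same values throughout, so each array was counted as 1 sample. With 3 arrays per group, their number limits the precision.

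For each of the 18193 genes the probe set with the highest mean over the 9 arrays was used. Genes were tested when that mean reached the 30th percentile of all gene means, which was 5.72 on the log2 scale and left 12735 genes. A linear model with the 3 groups was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend). The 4 contrasts were hairpin 1 minus scrambled, hairpin 2 minus scrambled, the mean of both hairpins minus scrambled, and hairpin 2 minus hairpin 1. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and an adjusted p below 0.05 counted as a change. All p-values are two-sided. Fold changes are antilogs of differences between mean log2 values, and are compressed where a gene lies near the floor or the ceiling of the array.

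Before the data were examined, 21 gene lists were fixed: adipocyte markers, adipogenic transcription factors, insulin signalling, lipid and energy metabolism, inflammation and interferon, matrix, cell cycle, stress responses and markers of other cell types. Each list with at least 5 measured members was tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the lists. The same test with a correlation estimated from the data and fry, which asks whether the genes of a list move on balance in 1 direction without reference to other genes, were run beside it. The named genes were also fixed by a rule: Ebf1 and its paralogs; the 10 highest and 10 lowest mean log2 fold changes among genes changed the same way with both hairpins; the 5 highest and 5 lowest for each hairpin and for hairpin 2 against hairpin 1; and from each list the 4 measured members with the smallest p in the mean of both hairpins. Gene models without a proper name were skipped outside the lists. The design, tests, lists, naming rule and most alternatives were chosen before the data were examined. Genes outside the rule are named in places as further members of a list, to show its members that moved together or apart, and those were chosen after their values were seen.

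The chain of tests was checked on simulated data with the mean of each gene on the scrambled arrays and the fitted spread. With 200 genes changed among 12735, the hairpin 1 and hairpin 2 contrasts each recovered 95.5% of genes changed by 0.5 log2 units and 100% of those changed by 1 or 2. Unchanged genes made up 4.74% of the calls for hairpin 1, and 6.95% for hairpin 2 and for the mean of both. The oxidative phosphorylation list was shifted as well, by 0.5 log2 units. In camera this 1 list was recovered and 0 others were called. Noise was drawn independently for each gene, so the check does not cover correlation between genes. In the data that correlation was estimated at 0.466 for the interferon list. To measure what shared control arrays add to the resemblance of the hairpins, 100 data sets with unchanged groups were simulated.

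The alternatives tried were no low-signal filter, a filter at the 50th percentile, the mean of all probe sets of a gene, quantile normalization of the deposited values, equal array medians, eBayes without trend, array quality weights, the repeat number as a block, fits over the groups compared alone, a minimum absolute log2 fold change of 1, and leaving out each array in turn. Python 3.11.15 with pandas 2.3.3 was used to join tables and matplotlib 3.10.9 to draw figures. Probe sets that name several genes or none were not used for genes. Raw scanner files were not used here.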

Results

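The arrays measured mRNA in mature 3T3-L1 adipocytes that carried a scrambled hairpin or 1 of 2 hairpins against Ebf1, with 3 arrays per group. The stated purpose of the series is to find the genes that depend on Ebf1 in fat cells. Groups separated clearly: the first principal component held 59.4% of the variance and ordered the arrays as scrambled, hairpin 1 and hairpin 2. The next held 24.3% and set hairpin 1 apart, with the first repeat of hairpin 1 at a score of -9.39 and its other repeats at -24.4 and -21.5.

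Ebf1 mRNA was lower with each hairpin. On its probe set with the highest signal, Ebf1 read 10.19 ± 0.10 on the log2 scale with the scrambled hairpin, 9.44 ± 0.11 with hairpin 1 and 8.94 ± 0.24 with hairpin 2 (SD, n = 3 each). This was a fall of 1.69-fold with hairpin 1 (log2 fold change -0.75, SE 0.113, limma adjusted p = 0.000102) and of 2.38-fold with hairpin 2 (-1.25, adjusted p = 2.98e-07). Hairpin 2 left less Ebf1 signal than hairpin 1 on this probe set, by -0.50 log2 units (adjusted p = 0.00351). Other Ebf1 probe sets differed by -0.61 and -0.52 (adjusted p = 0.0104 and 0.00784 over all probe sets). Another, at 10.13 on scrambled arrays, differed by -0.27 and did not pass (adjusted p = 0.316). Of the 5 Ebf1 probe sets, 4 fell with both hairpins, and the lowest signal left on a probe set was 46.7% of scrambled with hairpin 1 and 32.5% with hairpin 2. The fifth read 5.26 on the scrambled arrays, near the array floor, and did not pass the test with either hairpin (adjusted p = 0.572 and 0.604 over all probe sets). Among the paralogs, Ebf2 rose by 0.33 log2 units with hairpin 1 (adjusted p = 0.0163) and differed by 0.08 with hairpin 2, which did not pass the test (adjusted p = 0.61). The Ebf2 call was lost without the first or second scrambled repeat (adjusted p = 0.0504 and 0.0546) or repeat 2 or 3 of hairpin 1 (0.0756 and 0.0518). Ebf3, the paralog with the highest signal, differed by -0.02 log2 units with each hairpin, and Ebf4 lay below the signal filter.

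**Figure D1:**
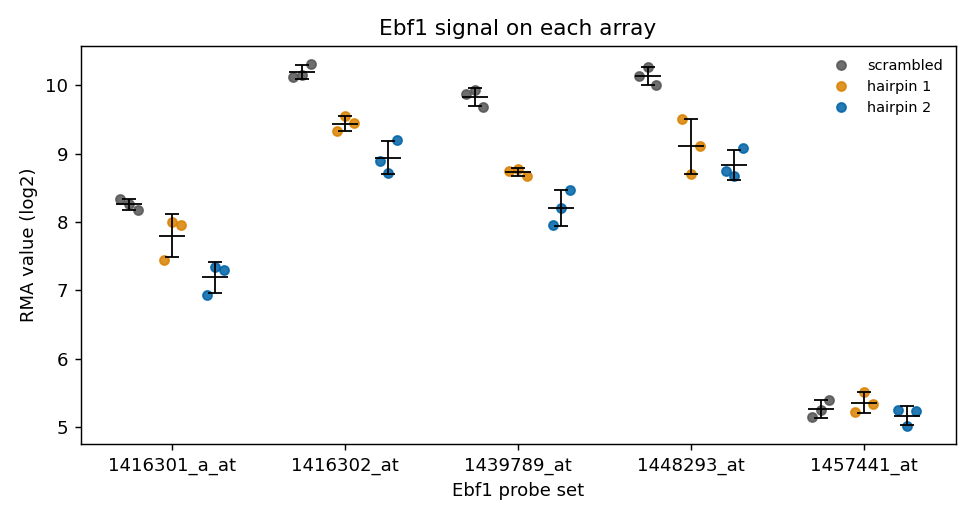
RMA value (log2) of the 5 Ebf1 probe sets on each of the 9 arrays; each point is an array, the wide line is the group mean and the error bar is the SD of 3 arrays. On 4 probe sets both hairpin groups lie below scrambled (10.19, 9.44 and 8.94 on the one with the highest signal), and the fifth stays near 5.26 in all groups.

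With hairpin 1, interferon-induced genes and the chemokine genes Ccl5, Cxcl10, Ccl2 and Ccl8 fell and matrix genes rose. The chemokine gene Ccl5 fell 46.7-fold, from 13.85 ± 0.06 to 8.30 ± 0.38 (SD, n = 3 each; log2 fold change -5.55, SE 0.167, limma adjusted p = 3.98e-12). Plscr2, a phospholipid scramblase gene, fell 15.9-fold, Cxcl10, an interferon-induced chemokine gene, fell 15.8-fold and Mx1, an antiviral GTPase gene, fell 12.4-fold. Colec11, which encodes a soluble lectin, fell 11.1-fold. Plscr2 and Colec11 ended at 5.00 and 5.28, near the array floor, and St6gal1 started at 6.05, so their folds are compressed and their ranks uncertain. The highest rises were those of Dpt, which encodes the matrix protein dermatopontin (5.08-fold), Fmod, which encodes the matrix proteoglycan fibromodulin (5.05-fold), the interleukin receptor subunit gene Il17re (4.77-fold), Lrrc17 (4.61-fold) and the sialyltransferase gene St6gal1 (4.56-fold). In all, 4199 of 12735 genes changed, 3023 higher and 1176 lower, and 127 higher and 125 lower by at least 1 log2 unit. After quantile normalization of the deposited values the split was 2459 higher and 1700 lower, so the share of higher genes fell from 72.0% to 59.1%. With array quality weights 7460 genes changed, 5238 higher and 2222 lower.

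Of the 21 lists, 7 shifted with hairpin 1, and none of these passed with an estimated correlation between genes (lowest camera adjusted p = 0.0665). Oxidative phosphorylation, the list of respiratory chain and ATP synthase subunits, rose with hairpin 1 by a small amount: 19 of 44 members rose (22 adjusted over the list alone) and 0 fell, with a median of 0.11 log2 units (camera adjusted p = 0.00234). The list was not called with an estimated correlation between genes (adjusted p = 0.543 with an estimated correlation), and its median was 0.07 with equal array medians. The median over all genes tested was 0.0675 with hairpin 1. Ndufs1, a complex I subunit gene, rose by 0.48 log2 units (SE 0.0568, adjusted p = 1.05e-05) and Atp5g1, an ATP synthase subunit gene, by 0.47 (adjusted p = 1.78e-05). The other 6 lists are those that shifted with both hairpins, described below by list.

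With hairpin 2 the chemokine genes Ccl5 and Cxcl10 and the antiviral gene Mx1 fell further than with hairpin 1. Ccl5 fell 232-fold, from 13.85 ± 0.06 to 5.99 ± 0.33 (SD, n = 3 each; log2 fold change -7.86, SE 0.167, limma adjusted p = 1.46e-14). Cxcl10 fell 50.7-fold, Cmpk2, a mitochondrial nucleotide kinase gene, 41.1-fold, the antiviral gene Oasl2 33.8-fold and Mx1 30.8-fold. The highest rises were those of St6gal1 (8.28-fold), Lrrc17 (7.0-fold), Plat, which encodes tissue plasminogen activator (6.83-fold), the serpin gene Serpinb9b (5.24-fold) and the cadherin gene Cdh13 (5.23-fold). Folds and ranks are compressed or uncertain where 1 group lies near or below the signal filter of 5.72, as for Ccl5 (5.99), Cmpk2 (6.29) and Mx1 (5.35) with hairpin 2 and for St6gal1 (6.05) and Serpinb9b (6.07) with the scrambled hairpin. In all, 4430 genes changed, 2740 higher and 1690 lower, and 243 higher and 180 lower by at least 1 log2 unit.

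Hairpin 2 shifted 8 lists, of which 2 were not called with hairpin 1. None of the 8 passed with an estimated correlation (lowest camera adjusted p = 0.0813). JAK-STAT signalling, the receptors and transducers of cytokine signals, fell: 9 of 26 members fell and 2 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.0248, median -0.09; adjusted p = 0.603 with an estimated correlation). Stat2, which transmits type I interferon signals and is also on the interferon list, fell (log2 fold change -1.94), as did the interferon receptor genes Ifngr2 (-0.80) and Ifnar2 (-0.43) and the oncostatin M receptor gene Osmr (-0.74). The list's call was lost without the first repeat of hairpin 2 (adjusted p = 0.0716). The unfolded protein response list fell, with 8 of 20 members lower and 4 higher (8 and 4 adjusted over the list alone; camera adjusted p = 0.0209, median -0.05; adjusted p = 0.463 with an estimated correlation). Its members Trib3 (-1.18), Creld2 (-0.86) and Edem1 (-0.54) fell. Neither list passed a direct test between the hairpins (camera adjusted p = 0.115 and 0.0852), although fry called both (adjusted p = 0.0222 and 0.00198). Over the alternatives the hairpin 2 medians ran from -0.23 to -0.05 for JAK-STAT and from -0.08 to -0.03 for the unfolded protein response.

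Interferon-induced genes fell with both hairpins, further with hairpin 2. Of 32 measured members of the list, 31 fell with hairpin 1 and 32 with hairpin 2 (31 and 32 adjusted over the list alone), and 31 fell with both. The median log2 fold change was -1.45 with hairpin 1 (2.72-fold, camera adjusted p = 7.2e-44) and -3.27 with hairpin 2 (9.64-fold, adjusted p = 2.9e-53). The call was lost when the correlation between genes was estimated (adjusted p = 0.0665 and 0.0813 with an estimated correlation). Oas1a, an antiviral oligoadenylate synthetase gene, fell with both (log2 fold changes -2.98 and -4.88), as did Ifit1 (-1.60 and -4.66), Psmb8, an immunoproteasome subunit gene (-2.39 and -3.89), and Usp18 (-1.93 and -4.49), which encodes a protease for the ubiquitin-like protein that interferon induces. Eif2ak2, the kinase gene that did not pass the test with hairpin 1 (-0.07), fell by 1.06 log2 units with hairpin 2. On the scrambled arrays these genes read high, Ifit1 at 13.81 ± 0.06 and Usp18 at 13.67 ± 0.03 (SD, n = 3 each). Genes of leukocytes and macrophages did not shift as a list: Laptm5 (-1.22 and -1.82) and Cd74 (-0.41 and -0.60) fell, Cd68 rose by 1.18 log2 units with hairpin 2 and did not pass with hairpin 1, and the other 6 of 9 measured members did not pass with either. With hairpin 1, Laptm5 no longer passed when all its probe sets were averaged (adjusted p = 0.178), nor Cd74 without the first scrambled repeat (0.0881) or the second of hairpin 1 (0.0843).

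Inflammatory mediators fell as a list with both hairpins, and its members did not all move alike. With hairpin 1, 14 of 29 members fell and 5 rose (14 and 6 adjusted over the list alone), and with hairpin 2, 18 fell and 4 rose (18 and 4 adjusted over the list alone). The medians were small, -0.11 and -0.27 log2 units (camera adjusted p = 1.26e-06 and 1.62e-05; adjusted p = 0.13 and 0.237 with an estimated correlation). Over the alternatives the medians ran from -0.21 to -0.0066 with hairpin 1 and from -0.36 to -0.16 with hairpin 2, and were nearest to 0 without a low-signal filter. The largest falls on the list included chemokine genes: Ccl2 (-1.97 and -2.51) and Ccl8 (-2.69 and -2.14) followed Ccl5 and Cxcl10. The list's 4 members that rose with both hairpins were Cxcl5 (0.56 and 2.13), the chemokine gene Cx3cl1 (0.89 and 1.67), the haptoglobin gene Hp (0.54 and 1.16) and Serpina3n (0.39 and 0.50).

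Fibroblast and matrix genes rose with both hairpins. Of 24 members, 23 rose and 0 fell with hairpin 1, 19 rose and 2 fell with hairpin 2 (23 and 0, and 20 and 2, adjusted over the list alone), and 19 rose with both. The medians were 0.68 and 0.57 log2 units (1.60-fold and 1.49-fold; camera adjusted p = 1.07e-14 and 1.35e-10; adjusted p = 0.13 and 0.237 with an estimated correlation). Over the alternatives the hairpin 1 median ran from 0.37, without a low-signal filter, to 0.81. The collagen gene Col1a1 rose by 1.69 and 1.98 log2 units, from 9.03 ± 0.08 to 10.73 ± 0.16 and 11.01 ± 0.06 (SD, n = 3 each), the fibronectin gene Fn1 by 1.27 and 1.61, and the proteoglycan genes Lum and Dcn by 1.58 and 2.00 and by 1.42 and 1.46. Dlk1, a preadipocyte marker, moved in opposite directions, 0.70 with hairpin 1 and -0.83 with hairpin 2. Col8a1, a collagen gene outside the list, rose by 2.01 and 1.68.

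Genes of cholesterol synthesis rose with both hairpins: 14 of 18 members rose and 1 fell with hairpin 1, 13 rose and 0 fell with hairpin 2 (14 and 1 with each adjusted over the list alone), and 12 rose with both. The medians were 0.38 and 0.27 log2 units (camera adjusted p = 1.03e-05 and 0.000149; adjusted p = 0.0665 and 0.113 with an estimated correlation). Sqle, which encodes squalene epoxidase, rose by 0.64 and 0.63 log2 units, Nsdhl by 0.60 and 0.59, and Hmgcs1, the gene of cytosolic hydroxymethylglutaryl-CoA synthase, by 0.36 and 0.51. Stard4, a sterol transfer gene, was the member that fell with hairpin 1 (-0.35), and it rose with hairpin 2 (0.29).

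Cell cycle genes rose with both hairpins: 19 of 29 members rose with hairpin 1 and 18 with hairpin 2 (19 with each adjusted over the list alone), 0 fell, and 14 rose with both. The medians were 0.41 and 0.33 log2 units (camera adjusted p = 2.51e-06 and 0.000274; adjusted p = 0.16 and 0.309 with an estimated correlation). With a filter at the 50th percentile the hairpin 1 median fell to 0.17. Ube2c, a mitotic ubiquitin-conjugating enzyme gene, rose by 1.15 and 1.41 log2 units, the topoisomerase gene Top2a by 1.08 and 0.66, and Birc5, the survivin gene, by 1.09 and 0.83, with scrambled levels of 7.41, 7.55 and 6.11. Targets of p53 fell as a list: 8 of 16 members fell and 2 rose with hairpin 1, and 8 fell and 0 rose with hairpin 2 (9 and 2, and 8 and 0, adjusted over the list alone). The medians were -0.21 and -0.23 (camera adjusted p = 0.00208 and 0.000274; adjusted p = 0.454 and 0.309 with an estimated correlation), and over the alternatives came as near to 0 as -0.08 and -0.12. Rrm2b, a ribonucleotide reductase subunit gene, fell with both (-0.62 and -0.90). Cdkn1a, which encodes a cell cycle inhibitor, fell with hairpin 2 (-1.18). It fell less with hairpin 1, a call lost without a low-signal filter (-0.23, adjusted p = 0.0559).

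**Figure D2:**
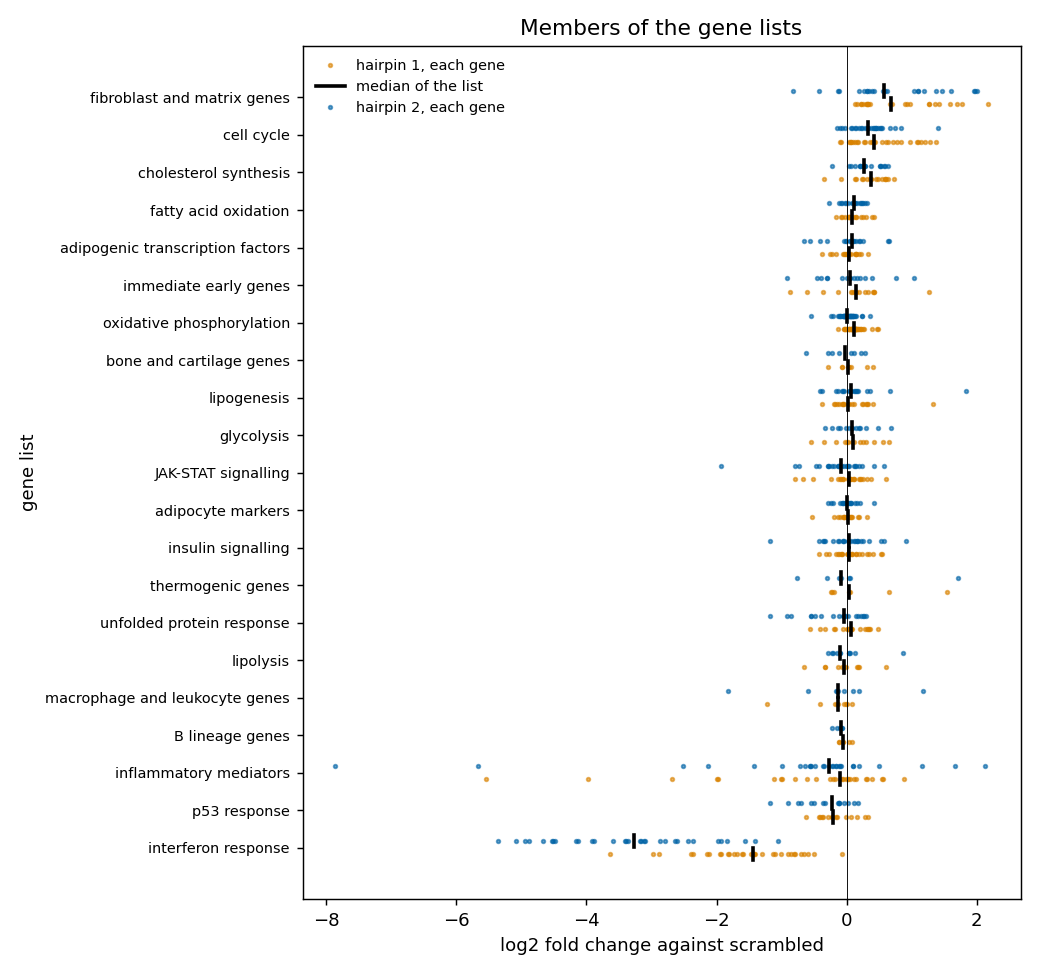
Log2 fold change against scrambled (horizontal axis) of each measured member of the 21 gene lists (vertical axis), in orange for hairpin 1 and blue for hairpin 2; each point is a gene and the black bar is the median of the list. The interferon list lies to the left with both hairpins (medians -1.45 and -3.27), and the fibroblast and matrix list to the right (0.68 and 0.57).

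Adipocyte markers did not shift with either hairpin. Their medians were 0.014 and 0.0094 log2 units (camera adjusted p = 0.42 and 0.941), and 0 of 19 members changed with both hairpins. With hairpin 1, 1 member rose and 2 fell (1 and 2 adjusted over the list alone); with hairpin 2, 3 rose and 3 fell (3 and 1 adjusted over the list alone). Pck1, a glyceroneogenesis gene, fell by 0.53 log2 units with hairpin 1 (adjusted p = 0.000879, and 0.0517 with the mean of its probe sets) and Car3 rose by 0.42 with hairpin 2 (adjusted p = 0.00241). The median member lay at the 98.5th percentile of probe set levels, where folds may be compressed. Falls were still measured at high levels with hairpin 1, as for Lamp1 (-0.46, from 14.25) and H2-K1 (-0.43, from 14.68). Both were chosen after their values were seen, and they do not show that the size of a fall is kept there. Among adipogenic transcription factors, which did not shift as a list (adjusted p = 0.42 and 0.941), Pparg, the master regulator of fat cell differentiation, fell with both (-0.25 and -0.56; from 13.50 ± 0.05 to 13.24 ± 0.04 and 12.93 ± 0.06; SD, n = 3 each). Srebf1, a regulator of lipid synthesis, fell with both (-0.38 and -0.41), and Klf15 with hairpin 2 (-0.66). Of 19 members, 1 rose and 2 fell with hairpin 1, and 3 rose and 4 fell with hairpin 2, the same counts as adjusted over the list alone.

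Insulin signalling genes went both ways and did not shift as a list (camera adjusted p = 0.766 and 0.843). Of 25 members, 6 rose and 2 fell with hairpin 1 and 6 rose and 5 fell with hairpin 2 (6 and 2, and 7 and 7, adjusted over the list alone). The insulin-like growth factor receptor gene Igf1r rose by 0.91 log2 units with hairpin 2, and the adaptor gene Grb14 by 0.53 and 0.57 with hairpins 1 and 2. Igf1r also rose with hairpin 1, a call lost after quantile normalization (0.23, adjusted p = 0.0518) among other alternatives. The regulatory subunit gene of phosphoinositide kinase, Pik3r1, fell with both (-0.31 and -0.43), a call lost with both hairpins when all probe sets of the gene were averaged (adjusted p = 0.436 and 0.054).

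Other lists of lipid and energy metabolism were not called by camera with either hairpin. Fry called glycolysis with both hairpins (adjusted p = 0.0151 and 0.0179), and fatty acid oxidation (0.0368) and thermogenic genes (0.00803) with hairpin 1. In lipogenesis (camera adjusted p = 0.775 and 0.368), 8 of 20 members rose and 2 fell with hairpin 1 and 7 rose and 4 fell with hairpin 2 (8 and 2, and 8 and 4, adjusted over the list alone), led by the fatty acid elongase gene Elovl6, which rose by 1.32 and 1.83 log2 units. In lipolysis (adjusted p = 0.42 and 0.75), 1 of 11 members rose with each hairpin, the monoglyceride lipase gene Mgll, by 0.61 and 0.87, while 2 and 3 fell (3 rose and 3 fell, and 1 rose and 3 fell, adjusted over the list alone). In fatty acid oxidation (adjusted p = 0.42 and 0.314), 6 of 18 rose and 0 fell with hairpin 1, and 8 rose and 2 fell with hairpin 2 (7 and 0, and 8 and 2, adjusted over the list alone). Acadvl (0.39 and 0.23) and Cpt2 (0.43 with hairpin 1) rose with both. The hairpin 2 call of Cpt2 was lost with the mean of its probe sets (0.10, adjusted p = 0.262). Of 7 measured thermogenic genes (adjusted p = 0.775 and 0.843), 2 rose and 0 fell with hairpin 1 and 1 rose and 2 fell with hairpin 2, the same adjusted over the list alone. Cox8b, a cytochrome oxidase subunit gene of brown fat and muscle, rose by 1.54 and 1.71 log2 units, and Cidea fell by 0.76 with hairpin 2. In glycolysis (adjusted p = 0.487 and 0.314), 6 of 14 rose and 1 fell with hairpin 1 and 4 rose and 0 fell with hairpin 2, the same adjusted over the list alone, among them the glucose transporter gene Slc2a1 (0.56 and 0.69) and Pkm (0.42 and 0.48).

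Immediate early genes were not called by camera (adjusted p = 0.625 and 0.941), while fry called them with hairpin 1 (adjusted p = 0.00593): 6 of 16 rose and 3 fell with hairpin 1, and 4 rose and 4 fell with hairpin 2 (6 and 3, and 4 and 5, adjusted over the list alone). Ccn1, also a matrix list member, rose by 1.27 and 1.04 log2 units, and Egr1 fell by 0.87 with hairpin 1. Bone and cartilage genes did not shift (adjusted p = 0.775 and 0.65), with 2 of 8 higher and 1 lower with hairpin 1 and 1 higher and 2 lower with hairpin 2, the same adjusted over the list alone. The proteoglycan gene Ogn fell by 0.63 with hairpin 2. The B lineage list, genes that Ebf1 is known to control in B cells among them, had 6 measured members, at a median percentile of 49.4 among probe set levels, and 0 changed (list adjusted p = 0.42 and 0.314; medians -0.06 and -0.09). The macrophage and leukocyte list missed the threshold (adjusted p = 0.0552 and 0.486; 0 higher and 2 lower, and 1 higher and 2 lower, the same adjusted over the list alone). With hairpin 1 it passed without the first scrambled repeat (adjusted p = 0.049), repeat 1 or 3 of hairpin 1 (0.0389 and 0.0423) or any repeat of hairpin 2 (0.0366, 0.047 and 0.0444), with the mean of all probe sets (0.0426) and with the replicate block (0.0418). The median of a list and its test had opposite signs in several lists that were not called: the adipocyte, adipogenic factor and insulin lists with both hairpins, JAK-STAT, unfolded protein response and bone lists with hairpin 1, and oxidative phosphorylation and immediate early lists with hairpin 2. Camera tests a list against the other genes. The median over all genes tested was 0.0675 with hairpin 1 and 0.0238 with hairpin 2. With hairpin 1 these lists had medians above 0 and below that of all genes, and with hairpin 2 only some of them did. The median and the mean had opposite signs for adipocyte markers with hairpin 1 and for lipolysis and thermogenic genes with hairpin 2.

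The chemokine genes Ccl5 and Cxcl10 and antiviral genes such as Mx1 were among the genes that fell most with both hairpins, and the matrix genes Dpt, Col8a1, Col1a1 and Lum among the 10 that rose most. The 10 lowest by mean log2 fold change were Ccl5, Cxcl10, Mx1, Cmpk2, Plscr2, Mpeg1, Melk, Oas1a, Ifi47 and Colec11. Mpeg1, which encodes a pore-forming protein, fell with both (-3.30 and -4.74), as did the GTPase gene Ifi47 (-2.70 and -4.87). The 10 highest were St6gal1, Lrrc17, Dpt, Plat, Sertad4, Col8a1, Il17re, Col1a1, Ear3 and Lum, with St6gal1 at 2.19 and 3.05. In all, 1740 genes rose and 620 fell with both hairpins, 2360 together, where independent calls would give 650.4 and 156. After quantile normalization the split was 1546 and 889, a share of higher genes of 63.5% in place of 73.7%. With a log2 fold change of at least 1 either way with each hairpin, 73 rose and 95 fell, so 43.5% were higher and the excess of higher genes turned round. Another 197 genes moved in opposite directions, where independent calls would give 654. Both contrasts subtract the same scrambled arrays, so the calls are not independent. Shared controls raise the number of genes that move the same way and lower the number that move apart. The counts for independent calls are therefore not a fair reference, and the gaps from them do not measure how far the hairpins agree.

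The log2 fold changes of the hairpins correlated across genes with r = 0.716 (Spearman 0.577); genes are not independent replicates, so no p is given. Simulated unchanged groups that shared their control arrays gave a mean r of 0.499. The covariance was 0.116, against a simulated 0.00465, a difference of 0.111. The sign was the same for 69.5% of genes, against 66.6% in simulation, so shared controls alone nearly gave this share. In simulation 0.01 genes on average passed the same way with both. With all groups unchanged that number lies near 0 in advance, so it is no reference for the observed 2360. Spread between the shared control arrays accounts for little of the covariance, by the values above. The simulation drew on the spread within groups, so a deviation common to all 3 scrambled arrays is not covered. These arrays are too few to be divided between the hairpins.

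**Figure D3:**
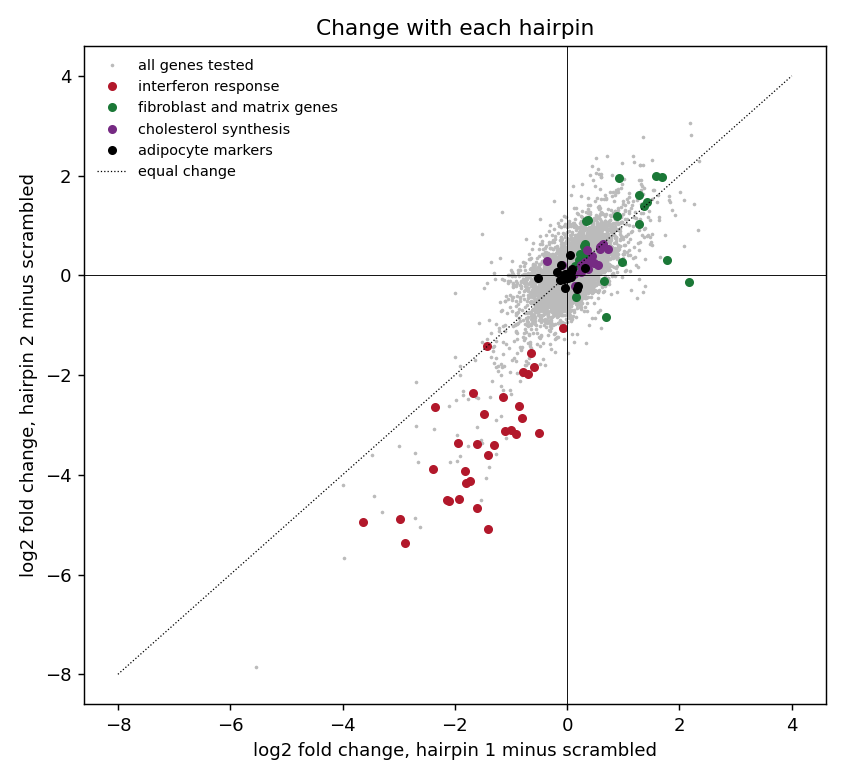
Log2 fold change of each of 12735 genes with hairpin 1 (horizontal axis) and hairpin 2 (vertical axis) against scrambled; grey points are genes, coloured points are members of 4 gene lists and the dotted line marks equal change. Interferon genes (red) lie at the lower left, mostly below the dotted line, and adipocyte markers (black) lie around 0 (medians 0.014 and 0.0094).

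In the mean of both hairpins, the direct test of Ebf1 hairpins against scrambled, interferon genes fell and matrix genes rose in 6 arrays against 3. All 32 interferon genes fell (32 adjusted over the list alone; median -2.42 log2 units, camera adjusted p = 1.05e-54; adjusted p = 0.0664 with an estimated correlation). Of the 24 fibroblast and matrix genes, 21 rose and 0 fell (22 and 0 adjusted over the list alone; median 0.67, adjusted p = 1.28e-14; adjusted p = 0.129 with an estimated correlation). In all, 4405 genes changed, 3036 higher and 1369 lower. After quantile normalization the split was 2709 and 1916, with 58.6% in place of 68.9% higher.

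The hairpins also differed from each other. Hairpin 2 had lower interferon-induced genes than hairpin 1: 30 of 32 members were lower and 0 higher (31 and 0 adjusted over the list alone), with a median of -1.95 log2 units (camera adjusted p = 6.7e-37; adjusted p = 0.193 with an estimated correlation). Oasl2 was 12.6-fold lower with hairpin 2 than with hairpin 1 (log2 difference -3.66, SE 0.114, limma adjusted p = 6.75e-12), Ifit1 8.34-fold, Slfn8 7.86-fold, Rtp4 6.29-fold and Apod, which encodes apolipoprotein D, 6.16-fold. Mmp2, which encodes a matrix metalloproteinase, was 5.41-fold higher with hairpin 2, the alanine aminotransferase gene Gpt2 5.13-fold, the versican gene Vcan 3.57-fold, Tmem176a 3.40-fold and Mlana 3.31-fold, from 5.25 with hairpin 1, near the array floor. Oxidative phosphorylation was lower with hairpin 2 than with hairpin 1, with 20 of 44 members lower and 0 higher (21 and 1 adjusted over the list alone; median -0.11, camera adjusted p = 0.000741; adjusted p = 0.893 with an estimated correlation). The matrix list did not pass the test between the hairpins (13 higher and 6 lower; 13 and 7 adjusted over the list alone; camera adjusted p = 0.156), and its median (0.12) and mean (-0.10) had opposite signs. In all, 3702 genes differed, 1483 higher and 2219 lower with hairpin 2, after quantile normalization 1954 and 2029, and with array quality weights 2178 and 3812 of 5990. Of the genes changed the same way with both hairpins, 772 also differed in size between them.

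**Figure D4:**
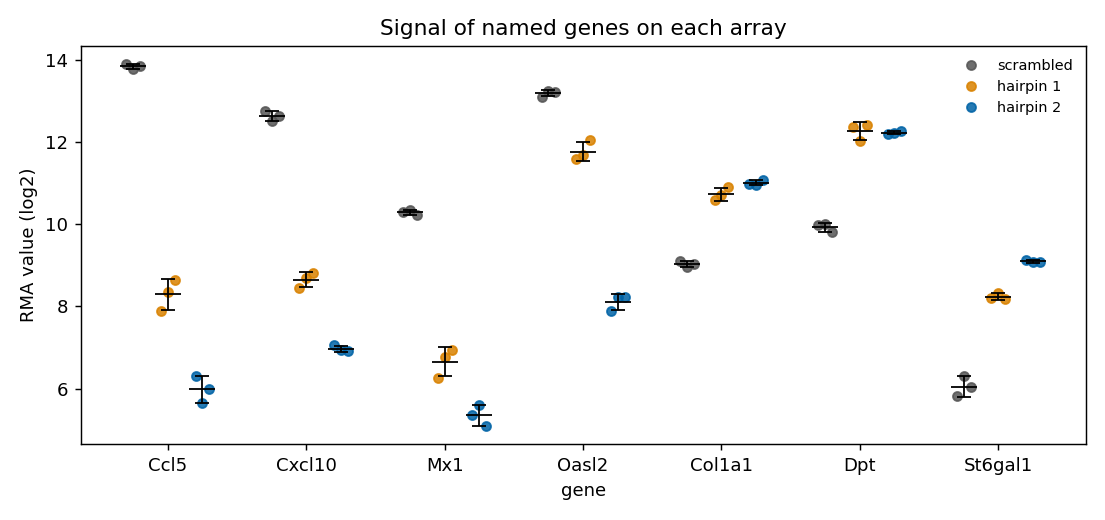
RMA value (log2) of 7 named genes on each of the 9 arrays; each point is an array, the wide line is the group mean and the error bar is the SD of 3 arrays. Ccl5, Cxcl10, Mx1 and Oasl2 step down from scrambled to hairpin 1 to hairpin 2 (Ccl5 13.85, 8.30 and 5.99), while Col1a1, Dpt and St6gal1 are higher with both hairpins.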

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

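The tests in this part were chosen after the pattern was seen, except the relation of interferon genes to Ebf1 within groups and the counts over other splits of the arrays.

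Interferon-induced genes were lower with hairpin 2 than with hairpin 1 by a median of -1.95 log2 units (median SE 0.104), which argues against a response raised on the scrambled arrays alone as the whole pattern. Leukocytes in the scrambled cultures are argued against as the main source, since they would bring their abundant transcripts. The upper quartile of the leukocyte list read 6.25 there, below 9.08, which is 10% of the interferon list's median level (12.4) on the linear scale. Ptprc at 4.76, Ctss at 5.07 and Tyrobp at 5.53 lay near the array floor. Levels of different probe sets can be compared only roughly. On the other side, Laptm5 read 10.48, above 9.08, and Cd14 9.02. Mpeg1, a gene named for its expression in macrophages and not on the list, was also among the genes that fell most with both hairpins. Laptm5 (-1.52) and Cd74 (-0.50) fell in the mean of both hairpins, while Cd68 (0.58) and Lyz1 (0.59), both near the array floor, rose. A part from leukocytes is therefore not ruled out. Within groups, the deviations of Ebf1 and of the interferon list from the group means correlated at r = 0.0215 over 9 arrays (exact permutation p = 0.954 within groups; rho = 0.3, p = 0.491; Benjamini-Hochberg adjusted p of the 2 relations 0.954; r = 0.0687 without the 2 farthest arrays), and the spread within groups is too small to decide. Ifnb1, the gene of type I interferon, was lower in the mean of both hairpins by -0.91 log2 units, so unequal induction of interferon by the 3 lentiviral vectors or their infections may account for the pattern. Ifnb1 fell with each hairpin (-0.87 and -0.96, limma adjusted p = 0.000234 and 6.27e-05). It did not pass between the hairpins (-0.09, limma adjusted p = 0.751). The interferon list did (camera adjusted p = 6.7e-37), though not with an estimated correlation (adjusted p = 0.193). With hairpins 1 and 2 Ifnb1 read 5.58 and 5.50, both below the signal filter, so its comparison between the hairpins cannot decide. Ifna1 did not pass with either hairpin (0.22 and 0.06). Both Ifnb1 and Ifna1 read near the array floor (6.45 and 5.97 on scrambled arrays) and do not decide. Because each vector is 1 group, unequal induction and an effect of Ebf1, which stays untested, cannot be told apart here.

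Fibroblast and matrix genes rose with both hairpins. A larger share of undifferentiated cells could raise them. Adipocyte markers had a median of -0.00644 in the mean of both hairpins (camera adjusted p = 0.574). They lie at the 98.5th percentile of levels, where folds may be compressed. Falls were measured at high levels with hairpin 1, as for Lamp1 (-0.46, from 14.25) and H2-K1 (-0.43, from 14.68). These genes were chosen after their values were seen, and they do not show that the size of a fall is kept there. The median of the list did not move clearly, but at these levels it cannot decide whether the share of undifferentiated cells grew. Pparg did fall with both hairpins, and a small rise of that share was not tested. Such a rise cannot be told apart from a change within the fat cells. The share of undifferentiated cells is argued against as the only source of the differences between the hairpins, where 13 members were higher and 6 lower with hairpin 2. A part from it is not ruled out there. A rise in proportion to the interferon fall is argued against: the median matrix difference between the hairpins was 0.115, where proportion would give 0.915, and the upper quartile of 0.295 lay below 0.458. An effect of Ebf1 itself stays open and untested, since Ebf1 and vector differ together between groups.

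Ebf1 itself differed between the hairpins by -0.50 log2 units in the direct test on its probe set with the highest signal, and the oxidative phosphorylation list by a median of -0.11. A set of 197 genes moved in opposite directions with the hairpins, 122 higher with hairpin 1 and 75 higher with hairpin 2. Chosen after their values were seen, Mmp2 (-1.17 with hairpin 1 and 1.27 with hairpin 2), Gpt2 (-1.52 and 0.84), Nus1 (0.33 and -1.37), Acox2 (1.24 and -0.45), Thbs1 (1.35 and -0.34) and Fst (0.59 and -1.05) had the widest gaps. Outside the genes used in the comparisons, 551 of 4400 probe sets with several gene names or none changed the same way with both hairpins, 367 higher and 184 lower.

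Other splits of the arrays were counted for each number of changed genes; they address chance between arrays and not between cultures, since the repeats may be technical (1 of 84 splits for the mean of both hairpins). For the mean of both hairpins, 1 of the 84 splits into 3 and 6 arrays, the real one, reached its count of 2611 in a fit with 2 groups. Chance between arrays is therefore unlikely there. Splits that mixed the groups gave 0 genes, so the count shows that the groups cluster, whatever the reason. The highest other split had 2012 genes and set the 3 hairpin 2 arrays against the rest, which is a structure of the groups. For genes changed the same way with both hairpins, 1 of 100 splits drawn, the real one, reached 2360, the highest other giving 1588. This makes chance between arrays unlikely. For hairpin 1, hairpin 2 and the difference between them, 1 of 10 splits each reached the real 4199, 4430 and 3702, the highest other giving 0, and 10 splits are too few for a share under 0.05.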

How the results depend on the processing

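The alternative without immune genes was chosen after seeing the data. All other alternatives were planned, and 0 fold changes of named genes and 0 lists that had passed changed direction. Ebf1 passed with both hairpins under each alternative run on single genes, which leaves out the minimum fold change. It lay between -0.81 and -0.70 for hairpin 1 and between -1.38 and -1.14 for hairpin 2 when each array was left out in turn. A minimum absolute log2 fold change of 1 left 252 genes for hairpin 1, 423 for hairpin 2, 289 for the mean of both, 183 between hairpins and 168 the same way with both, by construction. The last split into 73 higher and 95 lower, so the excess of higher genes among those changed with both hairpins turned round. Array quality weights gave 7460 genes for hairpin 1, 5990 between hairpins and a correlation of 0.667 between the hairpins' fold changes; the cause was not tested. The correlation was 0.742 with the mean of all probe sets, cause not tested, and 0.677 without the genes of the interferon, inflammatory, MHC and GTPase lists, which removes genes with large falls. Camera with an estimated correlation called 0 lists with both hairpins in place of 6, and fry 7, with glycolysis added. Leaving out each array in turn gave 3080 to 5423 genes for hairpin 1, 3567 to 5047 for hairpin 2, 3319 to 5404 for the mean, 2880 to 4664 between hairpins, 1771 to 2800 the same way with both, correlations of 0.672 to 0.725, and 6 lists each time. The highest of these counts came without the first repeat of hairpin 1, which stands apart on the second principal component.

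The replicate block kept each count within its range above and changed 3 calls among the named genes and lists, losing Adcy6 with hairpin 2 and adding G0s2 and the leukocyte list with hairpin 1. It gave 4281, 4470, 4470 and 3761 genes for hairpin 1, hairpin 2, the mean and the difference, and 2415 the same way with both. The arrays gave no clear sign that the repeat numbers pair them. Deviations of same-numbered arrays correlated between -0.293 and 0.250, above 0.1 in 3 of 9 pairs, and 5 of 9 correlated best with their own number. With so few arrays per group this does not exclude a pairing, and the titles do not say. Of 185 changes of named genes, 161 passed under every alternative run on single genes and 24 were lost under at least 1, among them Cdkn1a and Ebf2 with hairpin 1, Pik3r1 and Ddit3 with both, and Prdm16 with hairpin 2; 0 changed sign. The minimum fold change was applied to counts of genes only. Signal near the array floor or ceiling can limit folds, as for Ccl5 with hairpin 2, near the floor.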

Other observations

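The lists in this part were drawn up after the data were seen, so their tests describe these arrays. Genes of MHC class I presentation, which load and display peptides on the cell surface, fell with both hairpins: 13 of 13 members fell with each, 2 of them also on the interferon list, with medians of -0.83 and -1.33 log2 units (camera adjusted p = 5.39e-19 and 1.82e-18; adjusted p = 0.0265 and 0.0243 with an estimated correlation). The immunoproteasome gene Psmb9 (-2.37 and -3.08) and the peptide transporter gene Tap1 (-1.68 and -2.36) fell, and H2-K1, near the array ceiling at 14.68, fell less (-0.43 and -0.53). Interferon-inducible GTPases, which act against intracellular microbes, fell in 9 of 9 members with each hairpin, 4 of them also on the interferon list (medians -1.39 and -3.40, camera adjusted p = 1.16e-18 and 2.28e-21; adjusted p = 0.0265 and 0.0243 with an estimated correlation). Iigp1 (-1.26 and -3.59) and Irgm2 (-1.39 and -3.84) were among them. Of 12 genes of nucleic acid sensing and interferon ligands, 3 of them also on the interferon list, 6 fell and 1 rose with both hairpins, with Tlr3 lower (-0.94 and -1.67) and Ticam1 higher (0.51 and 0.53) (list adjusted p = 2.22e-05 and 9.31e-05; adjusted p = 0.089 and 0.116 with an estimated correlation).

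Complement genes moved apart: of 8 members, 2 fell and 1 rose with both hairpins, Cfb, which encodes complement factor B, among those that fell (-1.59 and -2.46), and the list was not called (camera adjusted p = 0.0574 and 0.64). Small leucine-rich proteoglycans rose with hairpin 1 as a list (median 0.87, adjusted p = 0.00187; adjusted p = 0.155 with an estimated correlation) and were not called with hairpin 2 (median 0.44, adjusted p = 0.227). Lum and Dcn, which are also on the matrix list, Fmod and Aspn (1.43 and 0.80) rose with both hairpins, and Prelp fell with both (-0.56 and -0.74). Oxidant defence genes rose with hairpin 2 as a list (median 0.19, adjusted p = 0.0332; adjusted p = 0.447 with an estimated correlation), with Hmox1, the heme oxygenase gene, higher by 0.98 and Nqo1 by 0.67, and differed from hairpin 1 (median 0.13, adjusted p = 0.00172; adjusted p = 0.311 with an estimated correlation). Ribosomal protein genes (medians 0.07 and 0.03, adjusted p = 0.0574 and 0.64) and lysosome genes (medians -0.04 and 0.07, adjusted p = 0.109 and 0.842) were not called, although the galactosidase gene Gla rose by 0.41 and 2.01 log2 units. Melk, a kinase gene of dividing cells, fell with both (-3.44 and -4.43) while the cell cycle list rose with both hairpins.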
